A study of Mus musculus with 10 samples.

How the data were processed

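RNA was measured in 10 mouse libraries made from cells that were isolated by fluorescence-activated sorting from the calvarial sutures of mice at postnatal day 7. The labels give the genotype as wild type, whereas the protocol names mice that carry a Ctsk-driven Cre, and the sources used here do not settle which alleles the animals had. The labels put 5 libraries in a group called DDR2-plus and 5 in a group called PSC, an abbreviation that the labels do not expand, and number the libraries 1 to 5 in each group. Per the labels' protocols, RNA was taken up with a micro-column kit, cDNA was made and amplified from 1 ng of RNA with a full-length template-switching kit, libraries were made with a transposase kit, which does not mark the strand, and sequencing was paired-end with 50 cycles. Per the submitters' processing notes, the reads were placed on the mouse build mm10 and the analysis used DESeq. The aligner, the counting tool and the gene annotation are not given in the sources used here.

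The deposited values are whole-number counts per gene symbol, not normalized, per the file's values, which sum to a different total in each library. The authors' table holds 25239 gene symbols, each once. Total counts ranged from 43419129 in PSC 5 to 62021992 in DDR2-plus 4, so that 1 count was worth between 0.0146 and 0.0249 CPM (counts scaled to a common library size). Counts of amplified reads are not independent molecules, so intervals and floors given for low counts cover counting error only. Without strand, reads of a gene and of an antisense gene cannot be told apart. Of the 106 genes selected for naming, 9 share over 10% of their exonic bases with another annotated gene and carry that uncertainty: Fgfr3, Spp1, Irs1, Igf2, Tgfb3, Gas1, Spry1, Bnip3 and Neurod1. Genes with near-identical copies can lose or share their reads. The table holds 0 counts over all libraries for Hbb-bs, Hbb-bt, Hbb-b2 and Hba-a2, and at most 2 for the other globin rows, and Gapdh has 16166 counts in all, so these rows were not interpreted. The same caution applies to Cyp2a5, which has close relatives.

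Differences between the groups were tested with the quasi-likelihood test of edgeR 4.0.16 under R 4.3.3, with TMM factors, genes kept by filterByExpr, no covariates, and Benjamini-Hochberg adjustment with a threshold of 0.05. A size threshold of 1 on the log2 scale was applied to the same calls. Fold changes are DDR2-plus over PSC, and every CPM value was scaled by the TMM factors, for the genes outside the fit as well. Standard errors of log2 fold changes were derived from the fold change and the F statistic. Genes with 0 counts in a group were given a lower bound of the fold, set against 3 counts over the whole group. Genes with 1 to 3 counts were given a ratio with a 95% Poisson counting interval.

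Before the data were examined, 32 gene lists were fixed, of which the sex-linked list was not tested and 30 had at least 5 tested members. The lists of the IGF system and of craniosynostosis genes follow the subject of the study. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the lists. The same test with an estimated correlation and fry were run beside it. Camera compares a list with the other genes, whereas fry asks only whether its members move, on balance, one way. The rule for naming genes was also fixed beforehand. It takes all 9 genes of the list of sort surface markers, Ctsk included. Per direction it takes the 10 largest fold changes and the 5 smallest p among genes past the threshold with a mean of at least 10 CPM in the higher group and no overlap between the groups, leaving out unnamed gene models and receptor segments. From each list it takes up to 4 members past the threshold and up to 2 highly expressed ones that were not. Short lists of pineal, olfactory, astrocyte, Schwann cell and choroid plexus markers were added after the data were seen, as was a list of the enzymes of cholesterol synthesis.

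Single measures of the libraries were compared with exact permutation tests. The gene test was checked on simulated counts drawn from the means, spread and sizes of these libraries with 200 changed genes. Over the 15075 genes that step kept, edgeR recovered 17.9% of the genes changed 1.5-fold, 64.2% of those changed 2-fold and 87.9% of those changed 4-fold, and 4.2% of its calls were unchanged genes. Among the calls of DESeq2 17.3% were unchanged genes, and among those of limma-voom 3.5%. The simulation changed a far smaller share of genes than the 39.1% called in the real data, so its recovery may differ from the real one. It held no shift in composition and does not check the scaling. No pair of libraries of one group agreed within sampling noise, the lowest chi-square per degree of freedom being 40.9. The labels state 5 animals per protocol but do not say which animals gave which library, so p-values measure only the spread between these libraries, which may be technical.

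Alternatives fixed beforehand were DESeq2 1.42.0, RLE and upper-quartile factors, no filter, a filter of a mean of 5 CPM in either group, limma-voom without and with quality weights, the library number as a block, and leaving out each library in turn. Scaling by library size alone and a comparison of numbers 1, 2 and 4 of both groups were added after the data were seen. Other splits of the libraries into 5 and 5 were drawn 100 times from 126, the real one included. Positions come from the GENCODE M21 annotation of mm10, in which 24366 of the 25239 symbols were found, and all 106 genes selected for naming had one position. Some of the selected genes are not reported here. Python 3.11.15 with matplotlib 3.10.9 was used for the plots.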

Results

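Gene expression was compared between 2 cell populations sorted from the calvarial sutures, the fibrous joints between the bones of the skull vault, of mice at postnatal day 7. Both populations had 5 libraries. The study is on stem cells of the suture and their part in craniosynostosis, the early closure of sutures. DDR2-plus cells are named for DDR2, a collagen-binding receptor kinase of the cell surface, and the protocol names mice with a Cre recombinase driven by Ctsk, the gene of the collagen-degrading protease cathepsin K, while the labels give the genotype as wild type. Total counts were between 49843470 and 62021992 in the DDR2-plus libraries and between 43419129 and 58270419 in the PSC libraries. These totals did not differ beyond the spread between libraries (exact permutation test, two-sided p = 0.111). More genes had at least 10 counts in DDR2-plus, 15980 ± 187.1 against 14630 ± 154 in PSC, and the ribosomal RNA gene Rn45s was lower there, at 3596 ± 821.6 against 6935 ± 873.8 CPM (SD, n = 5 each; exact permutation test, two-sided p = 0.00794 for both). The first principal component held 51.7% of the variance and parted the populations.

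Ddr2, for which the DDR2-plus population is named, and Ctsk, which drives the Cre named in the protocol, were examined first. Ctsk (mm10 chromosome 3, 95499256 to 95509362, plus strand) was 2.74-fold lower in DDR2-plus, at 107 ± 15.2 CPM against 294 ± 15.0 CPM in PSC (SD, n = 5 each; edgeR adjusted p = 4.36e-07). Ddr2 mRNA (chromosome 1, 169972307 to 170110762, minus strand) was not higher in the population named for it. It stood at 112 ± 3.56 CPM in DDR2-plus and 152 ± 10.7 CPM in PSC, a log2 fold change of -0.44 (SE 0.0652; edgeR adjusted p = 0.000165). Sorting reads the surface protein, so mRNA is an indirect check of the label. Scaled by library size alone, a setting chosen after seeing the data, the Ddr2 log2 fold change was -0.17 (edgeR adjusted p = 0.0498). The list of 9 sort surface markers holds both of these genes, although Ctsk encodes a protease and is not a surface marker. Of the 9 genes, 5 fell, Ddr2 and Ctsk among them, and 0 rose, over all genes and adjusted over the list alone. Pdpn, which encodes podoplanin, was 1.98-fold lower, Ly6a, which encodes the stem cell antigen Sca-1, was 1.94-fold lower, and Itgav, an integrin chain, was 1.28-fold lower in DDR2-plus. Itgav lost its call when only numbers 1, 2 and 4 were compared, also a setting chosen after seeing the data (edgeR adjusted p = 0.0689), and under library-size scaling (edgeR adjusted p = 0.429). Its log2 fold change was -0.36 in the main fit, -0.38 with numbers 1, 2 and 4 and -0.09 with library size alone. Over the 20 alternative settings its adjusted p lay between 0.00249 and 0.429, and that of Ddr2 between 5.33e-09 and 0.0498. Cd200 (189 and 221 CPM), Eng (11.9 and 8.76 CPM), Enpep (3.06 and 3.57 CPM) and Thy1 (0.699 and 0.807 CPM in DDR2-plus and PSC) did not pass the test. With Ctsk included, the camera adjusted p of this list was 0.012, and adjusted p = 0.204 with an estimated correlation.

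Between the populations, 6022 of 15416 tested genes (39.1%) changed by edgeR. Of these, 3096 were higher and 2926 lower in DDR2-plus. At least 2-fold changes were found for 1532 higher and 926 lower genes. Among the 1532, 617 had a mean under 1 CPM in PSC. The groups did not overlap in 30.1% of tested genes, where chance gives 0.79%. The alpha chains of type I collagen, Col1a1 and Col1a2, took 22.8% ± 0.834 of all counts in PSC and 5.97% ± 1.46 in DDR2-plus (SD, n = 5 each; exact permutation test, two-sided p = 0.00794, the smallest that 5 against 5 can give). Scaling for this composition matters for the direction of small changes. With library size alone, 5421 genes were higher and 1538 lower, and the median log2 fold change of all tested genes moved from 0.04 to 0.31.

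Cartilage genes were higher in DDR2-plus almost throughout. Of 25 genes, 23 rose, 1 fell and 1 did not pass; adjusted over the list alone, 23 rose and 2 fell. Comp, a cartilage matrix glycoprotein (chromosome 8, 70373558 to 70382066, plus strand), was at 4439 ± 481 CPM against 702 ± 156 CPM, 6.32-fold higher. Acan (chromosome 7, 79053483 to 79115099, plus strand), which encodes the large proteoglycan aggrecan, was 4.83-fold higher, Hapln1, the link protein that ties aggrecan to hyaluronan, 5.73-fold, and Matn3, a matrilin, 4.80-fold (edgeR adjusted p of 4.55e-07 or less for these 4 genes). Mmp13, a collagenase of hypertrophic cartilage and bone, was at 1035 ± 199 and 1368 ± 284 CPM in DDR2-plus and PSC (log2 fold change -0.40, edgeR adjusted p = 0.0521). It passed as lower in 9 of 20 alternative settings, among them the library number as a block (edgeR adjusted p = 0.0309). The list median was 2.36 on the log2 scale. PSC libraries were not free of these transcripts, with the list at a median of 19.5% of its DDR2-plus level. The camera adjusted p was 6.63e-12, and adjusted p = 0.204 with an estimated correlation. Fry, which does not compare the list with other genes, gave an adjusted p of 8.22e-06.

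**Figure D1:**
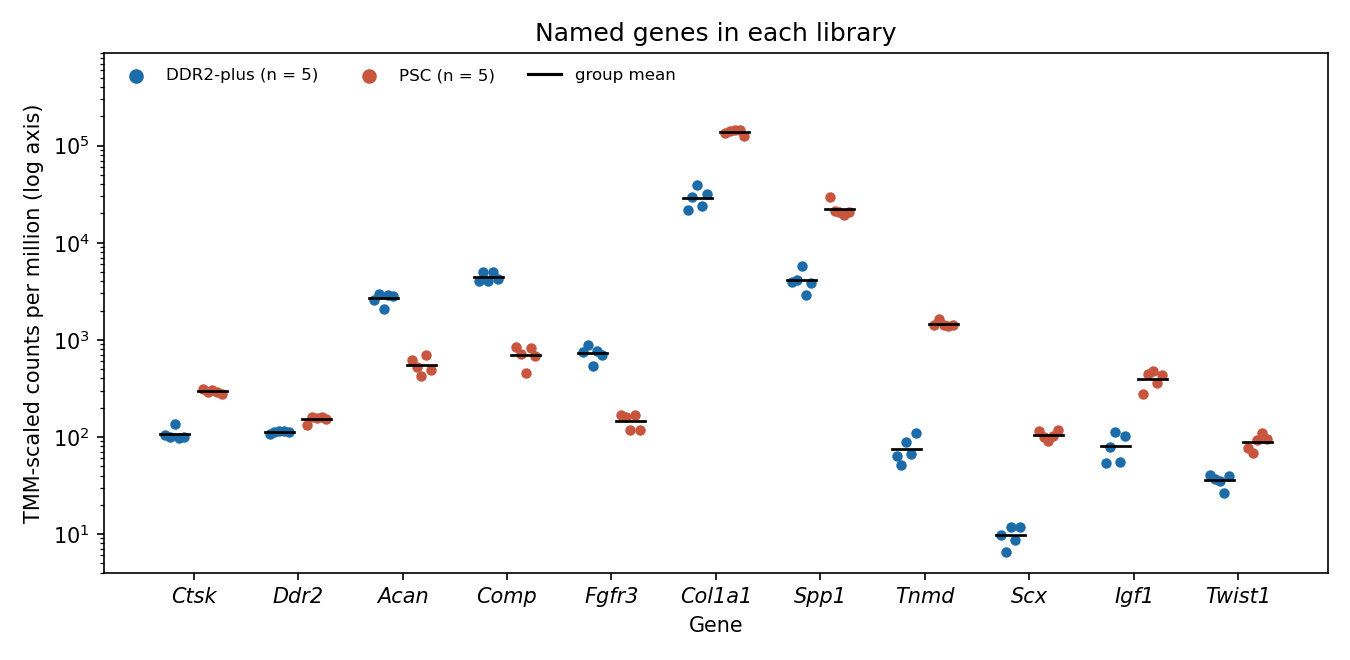
TMM-scaled CPM on a log axis for 11 genes in each library, as points, with the group mean as a bar. The 5 libraries of each population lie apart from those of the other for every gene drawn, with Tnmd at 75.9 CPM in DDR2-plus and 1451 CPM in PSC on average and Acan at 2673 and 553 CPM.

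Tendon genes showed the opposite direction. Tnmd (chromosome X, 133850980 to 133865577, plus strand), which encodes the tendon membrane protein tenomodulin, was 19.1-fold lower in DDR2-plus, at 75.9 ± 23.1 CPM against 1451 ± 99.4 CPM (log2 fold change -4.26, SE 0.188, n = 5 each; edgeR adjusted p = 6.24e-08). Scx (chromosome 15, 76457452 to 76459458, plus strand), the transcription factor scleraxis of tendon progenitors, was 10.9-fold lower, Thbs4, a thrombospondin of tendon and muscle matrix, 15.5-fold, Kera, the proteoglycan keratocan, 20.5-fold, Chodl, a membrane lectin, 17.0-fold, and Cilp2 4.17-fold. Of 15 tendon and ligament genes, 12 fell and 3 rose, over all genes and adjusted over the list alone (camera adjusted p = 1.64e-06; adjusted p = 0.204 with an estimated correlation). Of 14 periosteum genes tested, 10 fell and 2 rose (10 and 3 adjusted over the list alone), among them Aspn, the matrix protein asporin, 6.50-fold lower and Thbs2 4.20-fold lower (camera adjusted p = 1.36e-05; adjusted p = 0.204 with an estimated correlation). The periosteum list shares Tnmd, Kera and Tnc with the tendon list, so the results of these lists are not independent. It also holds Ctsk, Cd200 and Cxcl12, which count in other lists as well. Of 20 fibroblast genes, 16 fell and 2 rose, over all genes and adjusted over the list alone. Sfrp4, a secreted WNT inhibitor, was 7.06-fold lower, the matrix protein gene Fbln1 3.18-fold and Ogn, the proteoglycan osteoglycin, 1.85-fold, whereas Pcolce2, an enhancer of procollagen processing, was 5.74-fold higher and Smoc2 stood at 755 and 728 CPM without a call. Under library-size scaling Smoc2 passed the test as higher (edgeR adjusted p = 0.00299, the lowest of 20 alternative settings, the highest being 0.893). The camera adjusted p of the fibroblast list was 6.57e-07, and adjusted p = 0.294 with an estimated correlation.

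Osteoblast genes were mostly lower in DDR2-plus, with 17 of 24 down, 3 up and 4 not past the threshold, over all genes and adjusted over the list alone. Col1a1 (chromosome 11, 94936224 to 94953042, plus strand) was at 29132 ± 6853 CPM against 137940 ± 8118 CPM in PSC, 4.74-fold lower, and Col1a2 was 4.47-fold lower. Spp1, which encodes the bone matrix protein osteopontin, was 5.42-fold lower and Sparc, the matrix protein osteonectin, 1.91-fold (edgeR adjusted p of 8.04e-07 or less for these 4 genes). Among the members without a call, Runx2, the transcription factor that commits cells to bone, was at 116 ± 6.93 and 121 ± 12.1 CPM, and Alpl, the alkaline phosphatase of mineralizing cells, at 515 ± 115 and 558 ± 88.9 CPM in DDR2-plus and PSC, with edgeR adjusted p of 0.627 and 0.577. With library size alone Runx2 passed as higher in DDR2-plus, at 0.21 on the log2 scale (edgeR adjusted p = 0.0394, the lowest of 20 alternative settings, the highest being 0.995). The camera adjusted p of the list was 2.11e-06, and adjusted p = 0.334 with an estimated correlation.

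Of 24 genes used to mark suture and skeletal stem cells, 15 fell and 4 rose in DDR2-plus (16 and 4 adjusted over the list alone). Twist1 (chromosome 12, 33957671 to 33959829, plus strand), a transcription factor mutated in Saethre-Chotzen syndrome, was at 35.7 ± 5.75 CPM against 88.5 ± 16 CPM, 2.48-fold lower (edgeR adjusted p = 1.65e-05). Meox2, a mesenchymal homeobox gene, was 10.9-fold lower, Cxcl12, a chemokine of stromal cells, 2.56-fold, and Pdgfra, a receptor of mesenchymal progenitors, 1.87-fold. Lepr, the leptin receptor, was at 41.3 and 49.0 CPM and did not pass. The camera adjusted p was 0.000686, and adjusted p = 0.09 with an estimated correlation.

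The 17 tested genes of the IGF system, a list that follows the subject of the study, went both ways, with 5 higher and 6 lower (5 and 7 adjusted over the list alone; camera adjusted p = 0.267). Igf1 (chromosome 10, 87858265 to 87937042, plus strand), which encodes the growth factor, was at 79.9 ± 26.3 CPM in DDR2-plus and 397 ± 77.7 CPM in PSC, 4.96-fold lower (edgeR adjusted p = 5.24e-06). The genes of the IGF-binding proteins Igfbp6 and Igfbp5 were 7.55-fold and 3.36-fold lower, and Irs1, the adaptor downstream of the receptor, was 2.09-fold higher. Igf2 stood at 2701 ± 153 and 3032 ± 285 CPM without a call. It passed as lower in 3 of 20 alternative settings, among them the library number as a block (edgeR adjusted p = 0.041).

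Other signalling lists also split. Of 33 WNT pathway genes, 11 rose and 14 fell (11 and 15 adjusted over the list alone), with Nkd2, an inhibitor of the pathway, 8.57-fold lower, and the secreted inhibitor genes Wif1 and Dkk3 2.65-fold and 1.85-fold lower. Of 39 BMP and TGF-beta genes, 13 rose and 18 fell (14 and 18 adjusted over the list alone); Bmp2 was 2.22-fold higher, while Bmp3, Tgfb3 and the TGF-beta binding protein gene Ltbp3 were 1.97-fold, 1.98-fold and 1.73-fold lower. Among 13 hedgehog pathway genes, 3 rose and 5 fell (3 and 6 adjusted over the list alone). Ihh, the ligand made by prehypertrophic chondrocytes, was 8.03-fold higher at 295 ± 40.9 against 36.7 ± 15.3 CPM, its receptor gene Ptch1 was 1.61-fold higher, and the co-receptor gene Gas1 was 2.40-fold lower. Of 22 FGF pathway genes, 6 rose and 10 fell, over all genes and adjusted over the list alone. Fgfr3 (chromosome 5, 33721674 to 33737068, plus strand), a receptor of growth plate cartilage, was at 725 ± 126 against 146 ± 26.3 CPM, 4.96-fold higher (edgeR adjusted p = 4.55e-07), and Fgfrl1 was 2.50-fold higher. The ligand gene Fgf18 and the feedback inhibitor gene Spry1 were 4.25-fold and 5.12-fold lower. Of 16 Notch pathway genes, 3 rose and 5 fell, over all genes and adjusted over the list alone, with Notch3, Heyl and Rfng 2.74-fold, 2.42-fold and 1.71-fold lower. None of these 5 lists passed camera (adjusted p between 0.231 and 0.594).

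Of 30 genes linked to craniosynostosis, a list that follows the subject of the study, 10 were higher and 13 lower (11 and 13 adjusted over the list alone; camera adjusted p = 0.581). Besides Fgfr3 and Twist1, Wdr35, a ciliary transport gene, was 2.69-fold higher and Il11ra1, the interleukin-11 receptor chain, 1.97-fold lower in DDR2-plus. Of 25 genes of secreted factors that act on vessels or osteoclasts, 16 fell and 2 rose (18 and 2 adjusted over the list alone), with Slit3, Angptl4, Ptn and Angptl2 2.95-fold, 2.10-fold, 2.08-fold and 1.80-fold lower (camera adjusted p = 5.38e-06; adjusted p = 0.0644 with an estimated correlation).

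**Figure D2:**
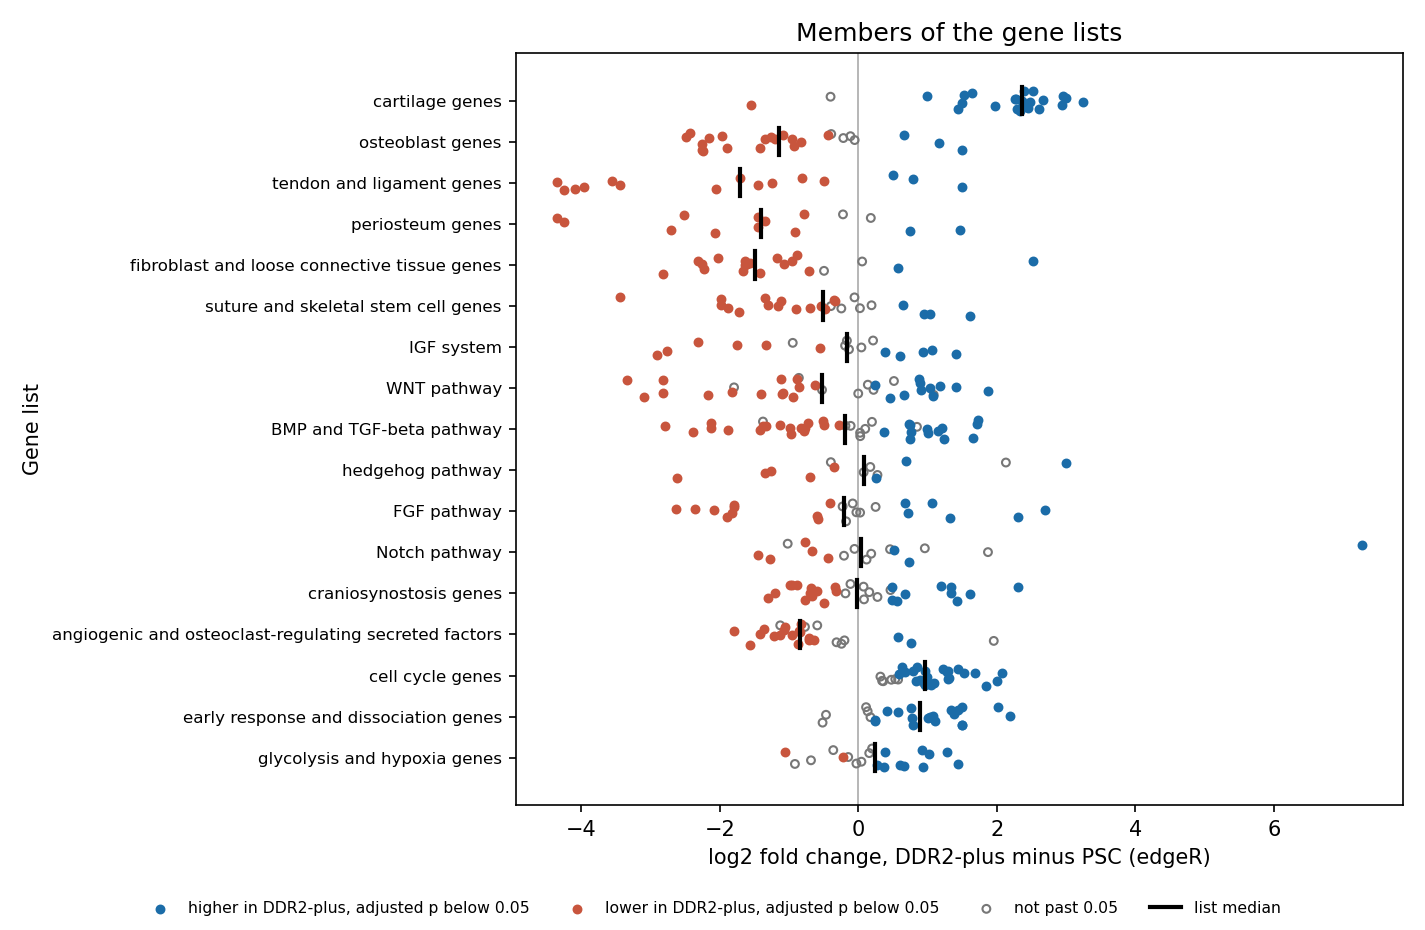
Log2 fold change (DDR2-plus minus PSC, edgeR) of each tested member of 17 gene lists, 1 point per gene, filled where the adjusted p is below 0.05 and open where it is not, with the list median as a bar. The cartilage list has its median at 2.36 and the tendon and ligament list at -1.71; the Notch pathway point above 7 is Mfng, which rests on 1 count in PSC.

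Cell cycle genes were higher in DDR2-plus. Of 30 genes, 23 rose and 0 fell (25 and 0 adjusted over the list alone). Cdk1, the mitotic kinase, was at 36.0 ± 7.45 against 14.8 ± 2.54 CPM, 2.44-fold higher, and the replication genes Mcm4 and Pcna were 1.86-fold and 1.55-fold higher (camera adjusted p = 1.73e-06; adjusted p = 0.335 with an estimated correlation). Genes of the early response, which also answer to tissue dissociation, moved with them: 19 of 24 rose and 0 fell, over all genes and adjusted over the list alone, with Dnajb1, a heat shock co-chaperone, 4.57-fold, Btg2 4.03-fold, Zfp36 2.81-fold and Socs3 2.11-fold higher (camera adjusted p = 4.11e-07; adjusted p = 0.38 with an estimated correlation). Of 20 glycolysis and hypoxia genes, 10 rose and 2 fell (10 and 3 adjusted over the list alone; camera adjusted p = 0.0541), among them Hk2, which encodes a hexokinase, 2.70-fold, Bnip3 2.43-fold and the glucose transporter gene Slc2a1 1.90-fold higher.

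The genes with the largest fold changes in favour of DDR2-plus belong to tissues other than bone. Rbp3 (chromosome 14, 33954003 to 33964216, plus strand), the retinoid-binding protein of photoreceptors and pinealocytes, was at 53.4 ± 19.8 CPM in DDR2-plus and had 2 counts over all PSC libraries, a ratio of 6040 (95% counting interval 1670 to 49900). Crx, a transcription factor of the same cells, had 2 counts in PSC, a ratio of 1320 (366 to 10900), and Cdhr1 had none, so that it was at least 945-fold higher. Slc17a6, the vesicular glutamate transporter of neurons, also had 0 counts in PSC and was at least 1130-fold higher. The neural transcription factor genes Neurod1 and Neurod4 were at 40.7 ± 34.5 and 19.1 ± 2.01 CPM against 0.0175 and 0.019 CPM. Without DDR2-plus 1, Neurod1 averaged 25.8 CPM in DDR2-plus, and without PSC 5 it averaged 0.00942 CPM and Neurod4 0.0113 CPM in PSC (Neurod4 0.0125 CPM without PSC 2). The water channel gene Aqp4 of astrocytes was at 30.5 ± 29.3 CPM, and at 19.2 CPM without DDR2-plus 4. The PSC counts of Rbp3, Cyp2g1, Cyp2a5 and Aqp4 all came from PSC 2 and those of Crx from PSC 3, so that these genes were at 0 in PSC without those libraries. The olfactory genes Gfy, Cyp2g1 and Cyp2a5 rested on DDR2-plus 5, with 84.4, 58.6 and 60.4 CPM there and at most 2.49, 8.17 and 7.28 CPM in the other 4 DDR2-plus libraries; under limma-voom they and Aqp4 did not pass (adjusted p between 0.0855 and 0.11). Over all alternative settings the adjusted p of these 4 genes lay between 1.31e-09 and 0.144. Without DDR2-plus 5, Gfy, Cyp2g1 and Cyp2a5 averaged 2.01, 3.68 and 3.37 CPM in DDR2-plus and passed in edgeR (adjusted p of 0.000308 or less).

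Marker lists gave the same picture. Of 13 neuron and brain genes tested, 12 were higher in DDR2-plus and 0 lower (13 and 0 adjusted over the list alone; camera adjusted p = 5.38e-06, adjusted p = 0.163 with an estimated correlation), including Snap25 at 17.0 against 0.0484 CPM and Map2 at 20.1 against 1.41 CPM. Of 12 Schwann and neural crest genes, 7 were higher and 1 lower (8 and 1 adjusted over the list alone; camera adjusted p = 0.00861, adjusted p = 0.163 with an estimated correlation), with the myelin gene Mbp 20.7-fold higher, Fabp7 31.4-fold and S100b, which chondrocytes also express, 4.26-fold. Summed over 8 pineal markers, a list chosen after seeing the data, DDR2-plus libraries held between 219.9 and 360.7 CPM and PSC libraries at most 1.78 CPM. Another 8 pineal markers, chosen without looking at their values, summed to 17.4 and 14.9 CPM (exact permutation test, two-sided p = 0.23). Of the 6 of these tested by edgeR, 3 were higher and 1 lower. Ttr, the main secreted protein of the choroid plexus, was at 680 ± 647 CPM against 3.43 ± 3.83 CPM, or 2.11 CPM without PSC 4. Of 10 epithelial genes, 7 were higher and 1 lower, over all genes and adjusted over the list alone (camera adjusted p = 0.0611), with Krt18 at 9.95 against 0.14 CPM and Krt15 at 12.9 against 0.618 CPM. Without PSC 2, Krt18 was at 0.0675 CPM in PSC.

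**Figure D3:**
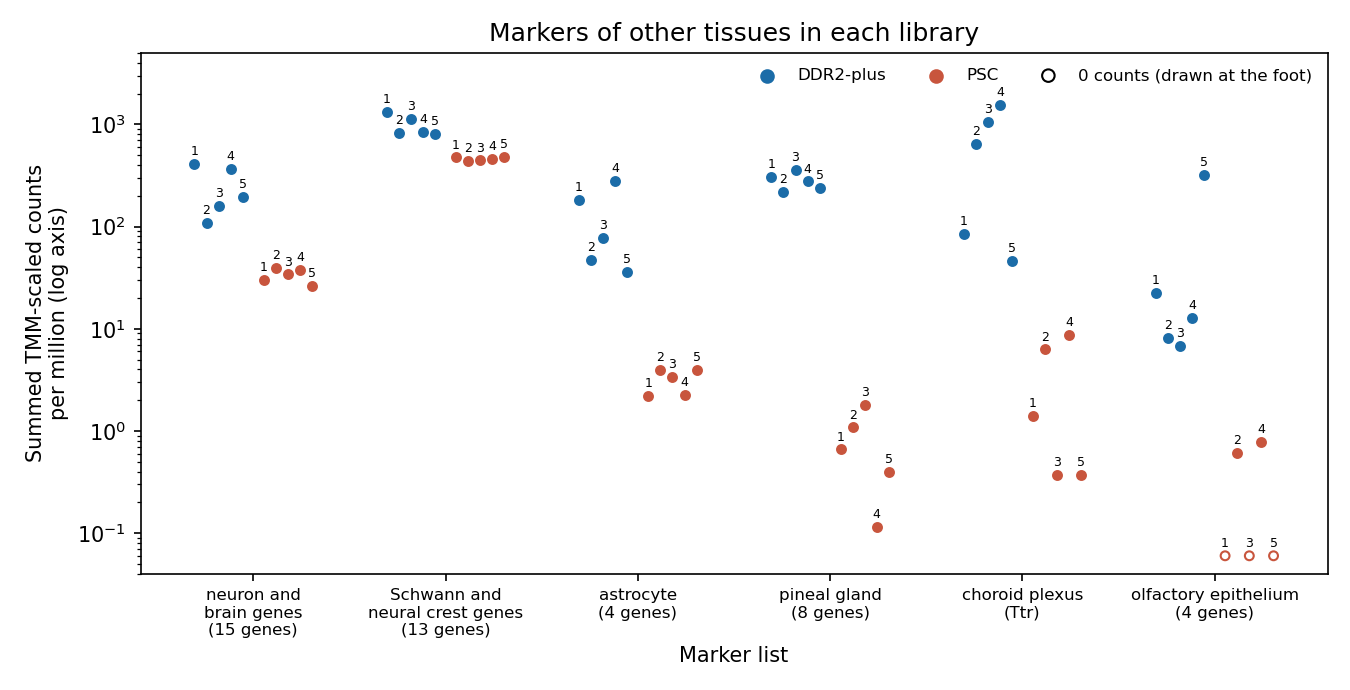
Summed TMM-scaled CPM on a log axis of marker lists of other tissues in each library, numbered as in the labels; open points at the foot stand for 0 counts. All 5 DDR2-plus libraries lie above all PSC libraries for the 8 pineal genes (at least 219.9 against at most 1.78 CPM), while the 4 olfactory genes peak in DDR2-plus 5 at 321 CPM.

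Of the blood cell lists, 5 of 16 neutrophil, 12 of 17 macrophage, 3 of 19 lymphocyte and 7 of 16 erythroid genes were tested. Among all tested genes 39.1% changed. None of 5 neutrophil genes passed, 1 of 12 macrophage genes rose (0 adjusted over the list alone), 1 of 3 lymphocyte genes rose and 2 of 7 erythroid genes rose (1 adjusted over the list alone). Summed macrophage markers stayed at or below 36.8 CPM in every library. Summed lymphocyte markers were at 109 CPM in DDR2-plus and 81.3 CPM in PSC (exact permutation test, two-sided p = 0.0238). Summed erythroid markers were at 19.6 and 6.18 CPM (exact permutation test, two-sided p = 0.0317). The macrophage and neutrophil sums did not pass (exact permutation test, two-sided p = 0.0794 and 0.571). These p-values were not adjusted over the lists. Of 12 endothelial genes, 4 rose and 3 fell, over all genes and adjusted over the list alone, Kdr, a VEGF receptor, being at 12.5 against 2.43 CPM, or 1.48 CPM without PSC 3. Of 11 pericyte and smooth muscle genes, 3 rose and 6 fell, of 13 skeletal muscle genes 2 rose and 0 fell, of 7 adipogenic genes 2 rose and 3 fell, and of 7 osteoclast genes 3 rose and 3 fell, each over all genes and adjusted over the list alone. Of 17 meningeal fibroblast genes, 5 rose and 10 fell, over all genes and adjusted over the list alone, with Mgp, a calcification inhibitor that cartilage also makes, 3.12-fold higher at 3809 ± 182 CPM. These lists did not pass camera (adjusted p between 0.0625 and 0.852, the lymphocyte list being too short to test). The median, the mean and the camera direction differed in sign for the hedgehog, Notch, craniosynostosis and neutrophil lists.

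Among the other genes named by fold or by p, Acly, which encodes the enzyme that makes cytosolic acetyl-CoA for lipid synthesis, was 3.25-fold higher in DDR2-plus at 333 ± 12.5 against 103 ± 9.84 CPM, and Gch1, the first enzyme of tetrahydrobiopterin synthesis, was 8.53-fold higher. In PSC, the smooth muscle myosin gene Myh11 was at 17.5 ± 5.90 CPM against 0.728 ± 0.772 CPM, or 0.391 CPM without DDR2-plus 5, and Tshr, the thyrotropin receptor, was at 10.3 ± 2.94 against 0.46 ± 0.303 CPM. Ptx4, Plxdc1, Ccl11, Cldn1 and Scube2 were 22.5-fold, 13.0-fold, 12.4-fold, 12.2-fold and 9.37-fold lower in DDR2-plus than in PSC (edgeR adjusted p of 7.16e-05 or less for these 5 genes).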

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

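The tests of depth, of summed marker levels, of the Aqp4 to Rbp3 ratio, of one axis of variation and of carry-over of the whole sort were chosen after the results they bear on were seen. Of 259 groups of 5 values examined, 27 had a library whose gap to the next exceeded the critical share of 0.71 of the range, where chance gives about 1 in 20, or 13.0. PSC 2 had 8 of them, DDR2-plus 5 had 7, PSC 1 had 4, DDR2-plus 3 had 3, DDR2-plus 1 and PSC 3 had 2 each, and PSC 5 had 1. In PSC 2, 4 of the 8 rest on a handful of counts.

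Each library is set here against the other 4 of its own population. Olfactory transcripts stood out in DDR2-plus 5, with 321 CPM over 4 markers, Gfy at 84.4, Cyp2g1 at 58.6 and Cyp2a5 at 60.4 CPM. Within DDR2-plus the same library had the highest Krt18 at 20.7 CPM, Myh11 at 2.08 CPM and Tgfb3 at 169 CPM. Of the DDR2-plus libraries, DDR2-plus 1 was highest in Neurod1 at 100.4 CPM and lowest in the share of its 10 leading genes at 20.4% of counts. DDR2-plus 3 was the highest of DDR2-plus in Ctsk at 134 CPM, where the other 4 lay between 97.8 and 104 CPM, and in Rbp3 at 87.9 CPM, and the lowest of DDR2-plus in Btg2 at 1696 CPM. Within PSC, PSC 1 was lowest in Ddr2 at 134 CPM and in Kera at 235 CPM and highest in Ihh at 63.9 CPM and Spp1 at 29305 CPM. Of the PSC libraries, PSC 2 was highest in Tnmd at 1627 CPM, Mcm4 at 33.3 CPM and the summed neutrophil markers at 43.1 CPM, and lowest in the summed pericyte markers at 624 CPM. It also held the few PSC counts of Rbp3 (0.045 CPM), Cyp2g1 (0.045 CPM), Cyp2a5 (0.0675 CPM) and Aqp4 (0.203 CPM). PSC 3 was the highest of PSC in Sfrp4 at 476 CPM and held the only PSC counts of Crx (0.0463 CPM). PSC 5 lay apart on the second principal component, at 98.2 where the other PSC libraries lay between -53.0 and -10.4.

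Transcripts of nervous, pineal, choroid plexus and olfactory tissue were found in the DDR2-plus libraries. The pineal, choroid plexus and olfactory lists chosen after the data were seen were hardly found in PSC. Depth is argued against for the neuron and brain list, which was fixed before the data were examined. That list had 13.5% of the PSC counts predicted at its DDR2-plus level, with at most 39.6 CPM in a PSC library. In a DDR2-plus library it had at least 108 CPM. The pineal, choroid plexus and olfactory lists had at most 0.5% each, again without overlap between the populations. As these lists were chosen after the data were seen, their share does not test depth. Pooled, 24 other markers of these 3 tissues, not looked at before, had 36.5%. They did overlap, at up to 54.8 CPM in PSC and down to 52.2 CPM in DDR2-plus, so depth is not settled for them. A single source with fixed proportions is argued against, because the ratio of Aqp4 to Rbp3 counts differed 11.1-fold between DDR2-plus libraries. Cells of tissues next to the skull that entered the DDR2-plus sort are a candidate source: of 32 markers not looked at before, 87.5% had a higher mean in DDR2-plus (random matched lists had a median of 59.4% and an upper limit of 75.0%), though some differences were slight, edgeR called 17 higher and 2 lower of 25 tested (olfactory 6 and 0 of 6, brain 4 and 0 of 6, pineal 3 and 1 of 6, choroid plexus 4 and 1 of 7), and their summed levels were higher for olfactory (45.7 and 0.835 CPM, exact permutation test, two-sided p = 0.00794; 9.83 CPM without DDR2-plus 5 and 0.508 CPM without PSC 5) and brain markers (37.0 and 11.3 CPM, p = 0.00794) but did not pass for pineal (17.4 and 14.9 CPM, p = 0.23) and choroid plexus markers (56.9 and 28.3 CPM, p = 0.135). The random lists drew each gene separately, whereas markers of the same tissue can move together. Their upper limit may thus be too narrow, and the share does not exclude chance. The most abundant of the 32 markers were modest, with Stoml3 at 15.4 CPM (65.6 CPM in DDR2-plus 5, 2.83 CPM without it) and Clic6 at 14.8 CPM. Of the 32, 11 also reached 1 CPM in PSC. The labels describe no gate that would have removed cells of these tissues, and expression by the DDR2-plus cells themselves was not tested.

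Cartilage transcripts were high in DDR2-plus and still present in PSC. Scaling does not account for the difference, as the list median stayed at 2.36 or more under every other scaling. Carry-over of the whole DDR2-plus sort as the source in PSC is argued against by 15 of 8000 genes. The 8000 were taken by their DDR2-plus level alone (at least 10 CPM in every DDR2-plus library). The 15 stood in every PSC library under 0.5 of the level expected from carry-over in the proportion of the cartilage list (12.1% to 26.4%). Carry-over allows none. Tph1, for example, had at least 60.7 CPM in DDR2-plus and at most 1.37 CPM in PSC. The 15 include pineal and neural genes already seen to be nearly absent from PSC, such as Rbp3, Neurod1 and Slc17a6. The test thus restates that absence, and it does not bear on carry-over of cartilage cells alone. Across the PSC libraries the list varied along one axis more than 100% of 1000 matched random lists, with 70.4% of its variation there against a median of 40.3%, and its sum ranged from 18720 to 39260 CPM. The random lists were matched on mean expression only, so genes that vary together for any reason can exceed them. The test thus shows shared variation and not its source. A varying number of cartilage cells, or of cells with such a program, in the PSC sort is possible. The tests run do not part these, and a biological mixture within the population was not tested.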

How the results depend on the processing

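Scaling by library size alone and the comparison of numbers 1, 2 and 4 were chosen after seeing the data. The count of changed genes kept within 1.5 times of 6022 under every alternative run, from 4701 with numbers 1, 2 and 4 to 6959 with library size alone. Leaving out each library in turn gave 5176 to 6020 changed genes, 2594 to 3191 higher, 2582 to 2887 lower, 2197 to 2621 changed at least 2-fold and 12 to 15 lists, with a Ctsk log2 fold change of -1.56 to -1.43 and a Ddr2 log2 fold change of -0.49 to -0.43, all past the threshold. Library size alone gave 5421 higher, 1538 lower and 615 at least 2-fold lower genes, a setting that by construction leaves out the composition factors. Only the real split of 100 reached 6022 changed genes or 2458 changed at least 2-fold, the highest other giving 0. The others mix the populations, widening the spread, and cannot exclude chance. Nor is chance excluded for the 12 lists called by camera, as 16 of 100 splits gave as many, the highest other 15. All 15 of the others kept 4 libraries of a population together and so carry much of the real difference, while the 79 splits that kept 3 together gave at most 11. With an estimated inter-gene correlation 0 of 30 lists were called (5 at an unadjusted p under 0.05), while fry, which asks another question, called 23. No gene called both in the main fit and in an alternative differed in direction between them. No named gene or list called in the main fit turned direction in any setting. The sign of other genes that lost their call was not examined. Among named genes, calls were lost by Gfy, Cyp2g1, Cyp2a5 and Aqp4 with limma-voom, without and with weights, and by Itgav with library size alone and with numbers 1, 2 and 4. Calls were gained, of 20 alternatives, by Mmp13 in 9, Igf2 in 3, Cd200 in 2 and Smoc2 in 1, and by the epithelial list in 9, the glycolysis and hypoxia list in 6, the erythroid list in 5 (of 19), the meningeal list in 2, and the endothelial (numbers 1, 2 and 4, adjusted p = 0.00445, 0.888 at the highest), WNT and pericyte lists in 1 each.

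The labels do not say whether the library numbers pair the libraries. Correlations of deviations of same-numbered libraries were small, between 0.029 and 0.053, though each of the 10 libraries correlated best with its own number. The mean of these correlations, 0.036, exceeded that of every other of the 120 pairings, the highest being 0.03. An exact permutation test over pairings, chosen after seeing the data, gave a one-sided p = 0.0083, the smallest they can give. Xist was also high in numbers 3 and 5 of both populations. Same-numbered libraries may therefore share animals or another source of variation, which the correlations do not tell apart. The labels neither state nor exclude shared animals, and the main fit leaves the numbers out. With the replicate block, 5742 genes changed, 3054 higher and 2688 lower, 2461 of them at least 2-fold, with Ctsk at -1.47 and Ddr2 at -0.44 and 13 lists; Mmp13, Igf2 and the erythroid list were among those that gained a call, and no named gene or list lost one. Genes without a call turned sign as follows, the cause not being tested. Thy1 was at 0.24 with limma-voom, 0.18 with the block, between -0.5134 and 0.2822 leaving out single libraries (above 0 without DDR2-plus 4, PSC 2 or PSC 3), 0.05171 with library size alone and 0.14 with numbers 1, 2 and 4. Leaving out single libraries, Enpep was between -0.406 and 0.07657 (above 0 without PSC 2) and Runx2 between -0.0967 and 0.000734 (above 0 without PSC 1). With library size alone, Enpep was at 0.04721, Cd200 at 0.04731, Alpl at 0.16, Runx2 at 0.21 (where it passed), Lepr at 0.02334 and Igf2 at 0.10. The camera direction of uncalled lists turned, with medians of 0.87 for endothelial genes with the 5 CPM filter and 1.27 with library size alone, of -1.70, -0.26 and 0.16 for neutrophil genes without DDR2-plus 2, without PSC 5 and with library size alone (-1.70 to 2.542 over single libraries left out), of 0.39 for macrophage genes with library size alone and of -0.95 for adipogenic genes with numbers 1, 2 and 4. Depth limits the low genes, where 3 counts in a library equal 0.0439 to 0.0747 CPM.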

Other observations

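The tests in this part, the gene families and the genes named from them were chosen after the data were seen. Most enzymes of cholesterol synthesis were higher in DDR2-plus, with 17 of 20 genes higher and 1 lower by edgeR. The list median was 1.28 on the log2 scale and ranged up to 1.55 with library size alone. Camera was not run on this list, which was drawn up after the data were seen. Idi1 was at 76.2 ± 14.6 CPM against 17.1 ± 2.62 CPM in PSC, 4.46-fold higher (edgeR adjusted p = 8.9e-07). Hmgcs1 was 3.60-fold, Sqle 2.94-fold and Cyp51 2.84-fold higher. Acly, which supplies the pathway with acetyl-CoA, was among the 5 genes with the smallest p in the same direction.

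Collagen chains went both ways. Of 43 chains tested, 10 were higher and 23 lower in DDR2-plus, with 11 higher and 22 lower under library-size scaling. The higher ones included Col2a1 (6.09-fold, 81477 ± 10384 CPM), Col9a1 (5.59-fold), Col10a1 (7.74-fold), Col11a1 (2.70-fold) and Col27a1 (4.49-fold), and also Col17a1 and Col25a1, at 1.03 and 0.40 on the log2 scale. Among the lower ones were Col3a1 (4.80-fold, 29708 ± 5100 CPM in PSC), Col5a1 (4.27-fold), Col14a1 (5.00-fold) and Col18a1 (8.43-fold). Of 80 ribosomal protein genes, 66 were lower and 0 higher, a shift of -0.35 in the list median that depends on scaling: with library size alone 11 were lower and 2 higher. Of 4 tested Hox genes all were lower in DDR2-plus (3 or 4 when single libraries were left out; 6 lower and 1 higher with no filter), and the highest of their group means was 3.14 CPM (Hoxd8 in PSC).

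Xist, expressed from the inactive X chromosome of females, was at 16.8 and 26.8 CPM in DDR2-plus 3 and 5 and at 34.9 and 36.0 CPM in PSC 3 and 5, and at most 6.53 CPM in the other libraries, at least 5.35-fold apart within each population. The lowest level of a Y-linked gene in those 4 libraries was 2.99 CPM (Kdm5d in PSC 5), above the floor of 3 counts. Libraries 3 and 5 of both populations may therefore hold cells of both sexes, a hypothesis that the labels neither state nor exclude. Xist was above that floor in the other libraries too, the lowest being 1.43 CPM in DDR2-plus 2. The floor thus does not set libraries 3 and 5 apart, and cells of both sexes are not excluded in the others.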
